A study of Mus musculus with 4 samples.

How the data were processed

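The series measured where the acetyltransferase NAT10 sits on RNA in mouse 32D cells. The assay was eCLIP, in which UV light crosslinks proteins to the RNA they touch, an antibody pulls down the protein, and the attached RNA fragments are sequenced. According to the labels there were 2 libraries from NAT10 immunoprecipitates and 2 input libraries, all from wild-type cells grown with interleukin-3. Nothing in the labels says whether the libraries of a group came from separate cultures.

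The authors deposited 1 peak list for the whole series, with no value per library. Each of its 4206 rows gives a peak, its strand, 1 gene identifier and a class (3' UTR, exon or 5' UTR), and all but 5 rows a gene symbol. Per the file headers it has a p column and a fold column. The p column of the deposited list holds values above 3 and was read as -log10 p. Whether the authors adjusted these p-values is not given in the sources used here, and 400 is the ceiling of the column. The fold column of the deposited list was read as the log2 fold of immunoprecipitate over input. The reason was that most of its values fit a mean of log2 ratios of read counts, as the closing section describes. Both values per peak are the authors' own and were used only to describe and rank peaks within the list; they carry no error per peak. The genome build was GRCm39 per the submitters' processing notes. The aligner, the peak caller, the rule that joined the replicates, the cut-offs and the treatment of reads that map to several places are not given in the sources used here. The lowest values in the list were a log2 fold of 3.00 and a -log10 p of 3.07, so weaker binding cannot be seen, and a gene without a peak is not shown to be unbound. Library totals were not used here, so the depth behind each peak is unknown apart from the read steps described in the closing section.

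Rows for the same peak under 2 gene identifiers (34 peaks) were counted once in peak counts and under both genes in gene counts. Positions are those of the peak names, counted from 1. Gene symbols were matched to the RefSeq gene table of GRCm38.p6, by symbol and then by a synonym that belongs to 1 gene. Of 1626 symbols, 1609 matched. Since the builds differ, that table served for names, gene types and gene lengths and for no coordinate. The background of the list tests was its 21900 protein-coding genes, of which 1605 had a peak.

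The gene lists and the tests were fixed before the data were examined. The 23 lists were cytosolic and mitochondrial ribosomal proteins, translation factors, ribosome biogenesis, replication-dependent histones, spliceosome and SR proteins, hnRNP proteins, mRNA decay and modification factors, haematopoietic stem cell regulators, myeloid and mast cell genes, interleukin-3 signalling, p53 and apoptosis, cell cycle, oxidative phosphorylation, proteasome, chaperones, glycolysis, actin cytoskeleton and 5 control lists of genes typical of other cells. The share of list members with a peak was set against all other background genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. Median peak values were compared between classes with two-sided permutation tests of 100000 resamples, adjusted over the 3 pairs, with intervals of 95% from 2000 bootstrap draws. Shares have exact Clopper-Pearson intervals of 95%, which cover counting error only. Peaks of 1 gene are not independent, so shares and medians by class were repeated with 1 peak per gene. Tests of peak width, of the strongest peak and of the 3' UTR share of list members, of mitochondrial genes, of gene name families and of read steps were added after the data were seen.

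Genes named in the text follow a rule also fixed before the data were examined. It takes the 15 genes with the strongest peak by fold, the 5 genes with the most peaks, up to 4 members of each list with the strongest peaks, and always Nat10, Thumpd1, Myc, Gata2 and Kit. Outside this rule the matched non-coding genes and the mitochondrial genes are named in full, to describe RNAs other than nuclear mRNA. Genes chosen after their values were seen are marked as such in the closing section. Of the genes in the rule, some are not reported here.

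Several planned tests could not be run on a list without library values and without a genome of its build. These were the random placement of peaks within transcripts, the position relative to start and stop codons, the sequence content of peaks, the test of immunoprecipitate against input and the agreement of the replicates. The planned matching of random lists on exonic length was replaced by matching on the genomic span of genes. Feature classes were taken from the authors' own column.

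Alternatives used the stronger peaks (2099 peaks with a log2 fold above 4.60), 1 peak per gene, another background or another strength value. Those added after the data were seen merged touching peaks, left out mitochondrial peaks, counted bases, matched lists on gene length in 10000 draws, used the other lists as background or asked for 2 separate regions per gene. Peaks were joined into a region only where they touched in the genome. A stretch split by an intron therefore counts as separate regions, so the demand for 2 regions also selects on exon number and transcript length. The list test was tested on simulated data over 21900 genes. A list of ribosomal proteins with 80% of members bound and one of hnRNP proteins with 50% were recovered in 100% of simulations, stem cell regulators with 35% in 99% and the proteasome with 25% in 81%. Of unchanged lists 0.5% were called. That rate is for lists whose genes had the same chance of a peak as other genes. Differences in expression between genes were not simulated, so the rate does not cover calls that arise from them. The median test was tried on 60 random splits of the 2640 observed folds of 3' UTR and 5' UTR peaks, with fewer permutations than in the main test. It called 0% of splits without a difference and 100% of those with a log2 shift of 0.3. Shuffling single peaks removes the dependence between peaks of 1 gene, so these rates do not cover it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.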

Results

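NAT10, the enzyme that places N4-acetylcytidine (ac4C) on RNA, was mapped by eCLIP in 32D cells, an interleukin-3-dependent mouse line that the labels describe as derived from bone marrow. The purpose stated for the series was to find mRNA sites that NAT10 binds directly, as a way into its role in haematopoietic stem cells. There were 2 NAT10 immunoprecipitates and 2 inputs, summarised by the authors in 1 list of peaks. Fold and p of each peak are the authors' values, and no spread between the replicates could be computed from the list.

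The list held 4172 distinct peaks on 1629 gene identifiers. Of these peaks 2132 lay on the plus strand and 2040 on the minus strand. Peaks were short, with a median width of 79 nt (interquartile range 49 to 119 nt). The median log2 fold over input was 4.60, which is 24.3-fold, and values ran from 3.00 to 11.00. The folds of 82.6% of peaks took values that a single input read in each library would give, so most folds can rest on a minimal input count. The median -log10 p was 5.68 (interquartile range 4.10 to 10.6), and 34 peaks stood at the ceiling of 400. A single peak was listed for 762 gene symbols (46.9%), while 41 symbols had 10 or more. Many peaks were pieces of longer bound stretches: 751 peaks touched the next one, and joining such pieces left 3421 regions.

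The strongest peaks lay on mRNAs of varied function. Bin2, a membrane-bending protein of blood cells, had the highest log2 fold, 11.00, at chromosome 15, 100539265 to 100539308, in its 3' UTR. Mdm2, the ubiquitin ligase that restrains p53, followed with 10.41 at chromosome 10, 117525398 to 117525532, also in the 3' UTR. Cat, which encodes catalase, reached 10.17 in its 3' UTR at chromosome 2, 103284549 to 103284579. The mitochondrial mRNA mt-Nd2, for a subunit of respiratory complex I, reached 10.12 at positions 4682 to 4789 of the mitochondrial genome. Next came the phosphatase gene Ptpre (9.49, 3' UTR), Mtdh (9.30, exon), Frrs1 (9.08, exon), Uprt (9.06, 3' UTR), the splicing regulator Mbnl2 (9.05, exon) and the innate immune kinase Tbk1 (9.04, exon). The last of the 15 strongest were the translation factor gene Eif4g2 (8.94, on a peak of 3 nt in an exon), Rint1 (8.72, exon), the lamin B receptor gene Lbr (8.67, 3' UTR), Fyco1 (8.65, 3' UTR) and Vps37a (8.60, 3' UTR). In Bin2, Mdm2 and Cat the signal was packed into a short stretch. All 11 Bin2 peaks lay within 430 nt, all 11 Mdm2 peaks within 475 nt and all 6 Cat peaks within 368 nt. Whether these stretches hold repeats, or sequence shared with other places in the genome, was not checked.

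Other genes carried many peaks. Mecom, a transcription factor gene needed by haematopoietic stem cells, had the most, with 36 peaks in 20 separate regions. Its strongest peak reached a log2 fold of 8.44 at chromosome 3, 30006167 to 30006318, in the 3' UTR. Snrnp70, a protein of the U1 splicing particle, had 25 peaks in 17 regions, and Luc7l2, another U1-associated factor, had 22 in 19 regions. Mbnl1, a splicing regulator, and Mdm4, the partner of Mdm2 in holding back p53, each had 22 peaks in 14 regions. Regions are separate in the genome, so introns can add to these counts. Cdk6, a kinase of the G1 phase, had 20 peaks over 8585 nt of its 3' UTR.

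**Figure D1:**
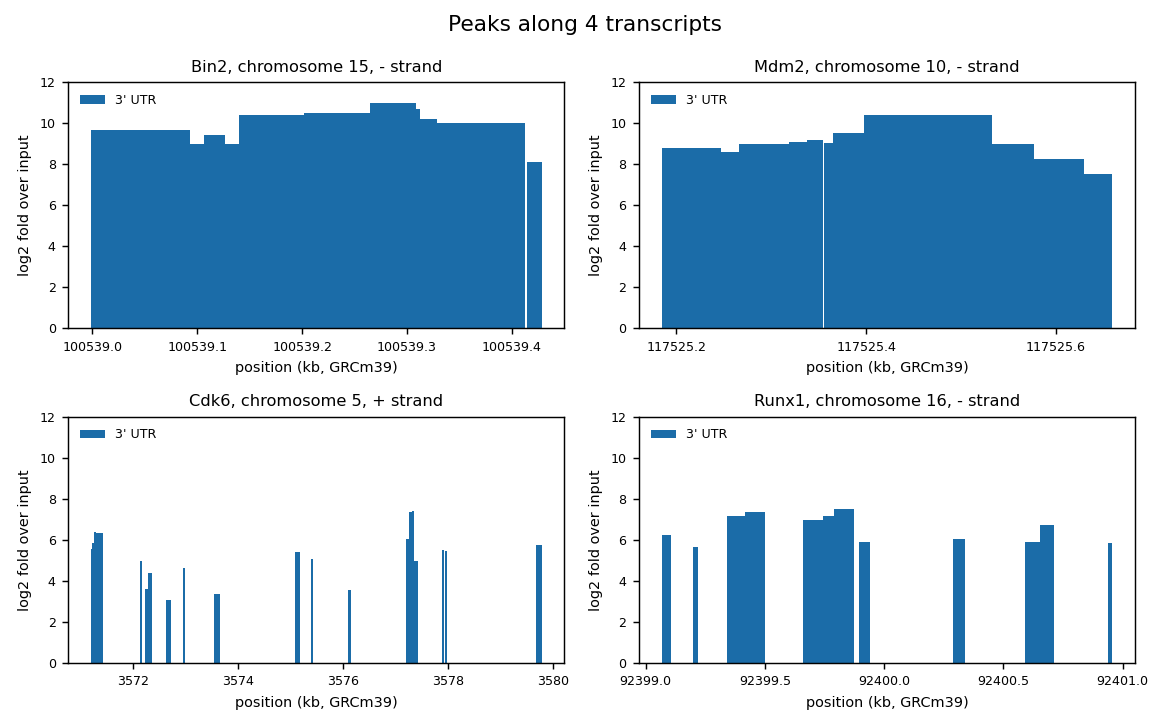
Peaks of Bin2, Mdm2, Cdk6 and Runx1 by position in kb (GRCm39) on the horizontal axis and log2 fold over input on the vertical axis, with 1 bar per peak drawn over its true width and coloured by the authors' class. The Bin2 and Mdm2 peaks cover 428 of 430 nt and 474 of 475 nt, while the 20 Cdk6 peaks and 12 Runx1 peaks are spread over 8585 and 1890 nt.

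Where NAT10 lay along its mRNAs was read from the authors' classes. The 3' UTR held most peaks, 2403 of 4172 (57.6%, 95% interval 56.1 to 59.1), on 1146 genes. The authors' exon class, apart from the untranslated regions, held 1532 peaks (36.7%, 35.3 to 38.2) on 700 genes, and 5' UTRs held 237 (5.68%, 5.0 to 6.43) on 148 genes. By gene, 856 gene identifiers (52.5%) had peaks in the 3' UTR alone, 386 in exons alone and 42 in the 5' UTR alone. Peaks in all 3 classes were listed for 32 genes, among them Mecom, with 23 in the 3' UTR, 10 in exons and 3 in the 5' UTR. Gata2, a transcription factor of stem and progenitor cells, had 1 peak of each class, with log2 folds of 5.04 in the 5' UTR, 4.32 in an exon and 3.55 in the 3' UTR. These shares have no random expectation beside them, since the lengths of the bound transcripts' parts were not used here.

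Fold differed little between these parts of the mRNA. The median log2 fold was 4.64 in 3' UTRs, 4.55 in exons and 4.50 in 5' UTRs. The 3' UTR exceeded the exon by 0.08 (95% interval 0.01 to 0.13; permutation test, p = 0.0239, adjusted p = 0.0718) and the 5' UTR by 0.14 (adjusted p = 0.0733), and neither passed the threshold. Exon and 5' UTR differed by 0.05 (adjusted permutation p = 0.441). Without the 61 mitochondrial peaks, all of them in exons, the 3' UTR exceeded the exon by 0.11 and passed (adjusted permutation p = 0.00084, range over the alternatives 0.00084 to 1). With 1 peak per gene the sign turned (-0.0083, adjusted permutation p = 0.940). Width did differ: 3' UTR peaks had a median of 86 nt, exon peaks 69 nt and 5' UTR peaks 68 nt. The difference of 17 nt from exons had an adjusted permutation p of 3e-05 and rests on the smallest p that these permutations can give. That of 18 nt from 5' UTRs had an adjusted permutation p of 0.0003. With 1 peak per gene the differences were 18 nt and 29 nt (adjusted permutation p of 3e-05 and 7.5e-05). Width was compared for single listed peaks, not for joined regions, and the lengths of exons were not used. These differences therefore do not show that NAT10 covers wider stretches in 3' UTRs.

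**Figure D2:**
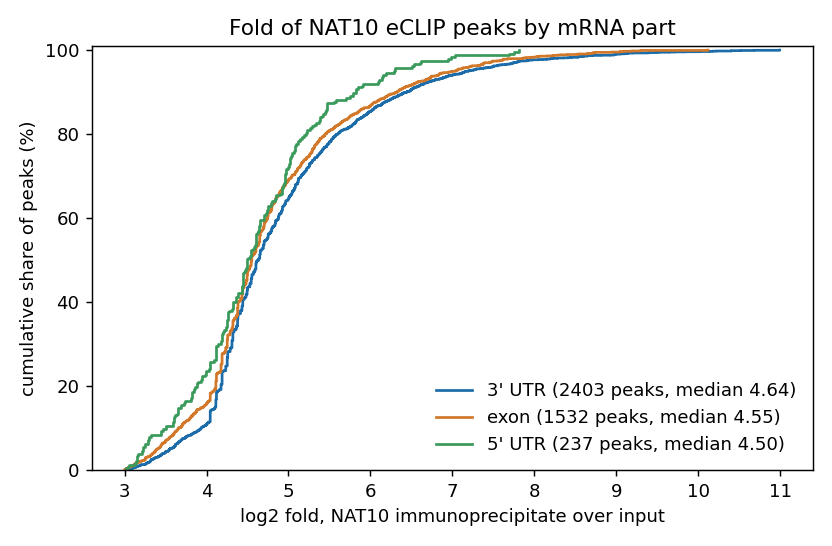
Cumulative share of peaks in percent (vertical axis) against the log2 fold of immunoprecipitate over input (horizontal axis), with 1 line each for 2403 peaks in 3' UTRs, 1532 in exons and 237 in 5' UTRs. The lines run close together, with medians of 4.64, 4.55 and 4.50.

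Which kinds of mRNA were bound was asked with the 23 gene lists. Of all 21900 protein-coding genes 7.33% had a peak. By Fisher's exact test with adjustment over the lists, 14 had a higher share than the other genes, 1 had a lower share and 8 were not called. The highest share belonged to cytosolic ribosomal proteins, the parts of the translating ribosome, with 70 of 86 members bound (81.4%, fold 11.6 over other genes, adjusted exact p = 6.1e-63). Among the strongest peaks there were those of Rpl23 (log2 fold 6.84), Rps25 (6.35) and Rpl28 (6.19), all in exons. Bound ribosomal protein genes had a 3' UTR peak in 32.9% of cases against 72.7% of other bound genes (Fisher's exact test, adjusted p = 2.6e-10). The lengths of the 3' UTRs were not used, so this test cannot separate the placement of NAT10 from the length of the 3' UTR. The strongest peak of bound ribosomal protein genes had a median log2 fold of 5.10, against 4.66 for other bound genes (permutation test, adjusted p = 0.0133). They also had more peaks, 309 on 70 genes, and with the median peak of each gene they stood at 4.28 against 4.46, so the direction turned and the call was lost (permutation test, adjusted p = 0.233, range over the alternatives 0.00017 to 0.233). Reads of these genes can be shared with their many pseudogenes. The ribosomal proteins of mitochondria had 2 of 79 members bound, Mrpl13 (5.26) and Mrpl24 (3.15), a share of 2.53% that did not pass the test (adjusted exact p = 0.172).

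Of the hnRNP proteins, which coat pre-mRNA and direct its splicing, 21 of 28 were bound (75%, fold 10.4, adjusted exact p = 7.1e-18). Examples were Hnrnpu (7.27), Hnrnpa2b1 (6.79) and Hnrnpa1 (6.26), each with its strongest peak in the 3' UTR, and Raly (6.58), whose peak lay in an exon. Spliceosome and SR proteins had 17 of 56 members bound (fold 4.18, adjusted exact p = 7.5e-07). Prpf39 (6.65) and Snrnp70 (6.64) led, then the SR proteins Srsf2 (6.12) and Srsf5 (5.63), each with its strongest peak in the 3' UTR. Among factors of mRNA decay and modification 18 of 54 were bound (fold 4.59, adjusted exact p = 7.4e-08). They included Zfp36l1 (6.27), which binds AU-rich elements, the decay kinase Smg1 (6.23), the deadenylase scaffold Cnot1 (6.07) and the decapping enzyme Dcp2 (5.44). This call was lost when 2 or more separate regions per gene were asked (fold 2.72, adjusted exact p = 0.0649, range over the alternatives 8e-07 to 0.966). Translation factors had 19 of 70 bound (fold 3.74, adjusted exact p = 9.6e-07), led by Eif4g2, Eef1a1 (6.36 and 20 peaks), Eif4g3 (6.34) and Eif4a2 (5.82). Ribosome biogenesis and nucleolar proteins, the group to which NAT10 itself belongs, had 7 of 60 bound and were not called (fold 1.59, adjusted exact p = 0.251). Npm1 (6.03), Dkc1 (4.65), Ncl (4.51) and Nop56 (4.50) were the strongest. Nat10 and Thumpd1, its partner in tRNA acetylation, had no peak in the list.

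Regulators of haematopoietic stem cells had 19 of 51 members bound (37.3%, 95% interval 24.1 to 51.9, fold 5.13, adjusted exact p = 4.7e-09). After Mecom came Runx1, a master regulator of blood stem cell formation, with 12 peaks and 7.50 at chromosome 16, 92399792 to 92399875. The ETS factors Erg and Fli1 reached 6.70 (3' UTR) and 6.67 (exon). Kit, the stem cell factor receptor, had no peak. Bound members had a median strongest peak of 5.37 against 4.69 for other bound genes, which did not pass after adjustment over 17 lists (permutation test, adjusted p = 0.0537). Interleukin-3 signalling, on which these cells depend, had 12 of 37 members bound (fold 4.45, adjusted exact p = 1.5e-05). Sos1, which activates Ras, reached 7.58 in an exon, and Pim1, a survival kinase, had 13 peaks in 4 regions, up to 6.02 in the 3' UTR. Myc, the growth-promoting transcription factor, had a peak of 6.19 in its 5' UTR at chromosome 15, 61859286 to 61859412, and one of 4.50 in its 3' UTR. Jak1, the cytokine receptor kinase, reached 5.75 in its 5' UTR. Of the p53 and apoptosis genes 12 of 36 were bound (fold 4.58, adjusted exact p = 1.1e-05). Besides Mdm2 and Mdm4 (6.61) these included the survival gene Bcl2 (7.01, 3' UTR) and Casp8 (6.46, exon), the initiator caspase of death receptors. Myeloid and mast cell genes had 7 of 40 bound (fold 2.39, adjusted exact p = 0.0379). Gata2, the cytokine receptor subunit gene Csf2rb (5.0), the granule proteoglycan gene Srgn (4.75) and Ptprc (4.55), which encodes CD45, had the strongest peaks. This call was lost with the stronger peaks alone (adjusted exact p = 0.333), without receptor and predicted genes in the background (0.115) and against lists matched on gene length (0.0581, random lists). Against the other lists apart from the controls its direction turned (fold 0.545, adjusted exact p = 0.112); over the 5 alternatives the adjusted p ran from 0.0215 to 0.333.

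Actin cytoskeleton genes had 17 of 33 members bound (fold 7.09, adjusted exact p = 8.1e-11). The strongest peaks of Actb (8.57), Myh9 (7.12), Tmsb4x (7.03) and Pfn1 (5.50) all lay in the 3' UTR. Replication-dependent histones had 27 of 62 (fold 6.03, adjusted exact p = 2.4e-14), led by H4c4 (7.14), H2bc15 (6.10), H4c6 (5.99) and H2bc18 (5.72). With peaks in 2 or more separate regions asked of each gene, the histone call was lost (fold 1.89, adjusted exact p = 0.232, range over the alternatives 1.2e-12 to 0.232). That demand favours long transcripts of several exons, so this loss cannot separate a weak call from gene structure. Histone copies are near-identical, so the single histone gene behind a peak is uncertain. Chaperones had 16 of 38 (fold 5.79, adjusted exact p = 1e-08), among them Canx (6.78), Pdia4 (6.53), Hsp90aa1 (6.00) and Hspa8 (5.77). Glycolysis had 7 of 23 (fold 4.17, adjusted exact p = 0.0017), with Pfkp (5.15), Slc2a3 (5.12), Aldoa (4.84) and Pkm (4.61). The proteasome had 9 of 43 (fold 2.87, adjusted exact p = 0.0057), with Psmd5 (7.35), Psmd14 (5.18), Psmb4 (4.96) and Psme4 (4.90). No proteasome gene was left when 2 or more separate regions were asked (adjusted exact p = 0.517, range over the alternatives 0.0085 to 0.517). Oxidative phosphorylation had 12 of 88 (fold 1.87, adjusted exact p = 0.0523), with Cox7b (4.80), Cox7c (4.79), Atp5b (4.69) and Ndufa4 (4.57), and cell cycle genes had 7 of 59 (fold 1.62, adjusted p = 0.251), with Cdk6 (7.41), Top2a (5.88), Ccnd2 (5.05) and Cdc25c (4.96). Neither passed. Bound histone genes and bound oxidative phosphorylation genes had a 3' UTR peak less often than other bound genes, in 40.7% against 71.5% and in 25% against 71.3% (Fisher's exact test, adjusted p = 0.0071 for both). Here too the lengths of the 3' UTRs were not used, so a shorter 3' UTR is not separated from another placement.

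No control list lay above the background. Among olfactory receptors 1 of 1106 was bound, Olfr920 (4.64), which was lower than other genes (fold 0.01, adjusted exact p = 4.4e-35). No lymphoid gene of 23 and no hepatocyte gene of 29 had a peak (adjusted exact p = 0.448 and 0.31). Of 22 erythroid and megakaryocyte genes Itga2b was bound (4.25, adjusted exact p = 1), and the list of neuronal genes was not called (adjusted p = 0.755). The background could not be limited to genes transcribed in 32D cells, since no expression values were used here. When the other lists apart from the controls served as background, 2 lists remained higher instead of 14, cytosolic ribosomal proteins (fold 3.08, adjusted exact p = 1.9e-22) and hnRNP proteins (2.49, 1.2e-05), and haematopoietic stem cell regulators were no longer called (1.20, 0.534).

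**Figure D3:**
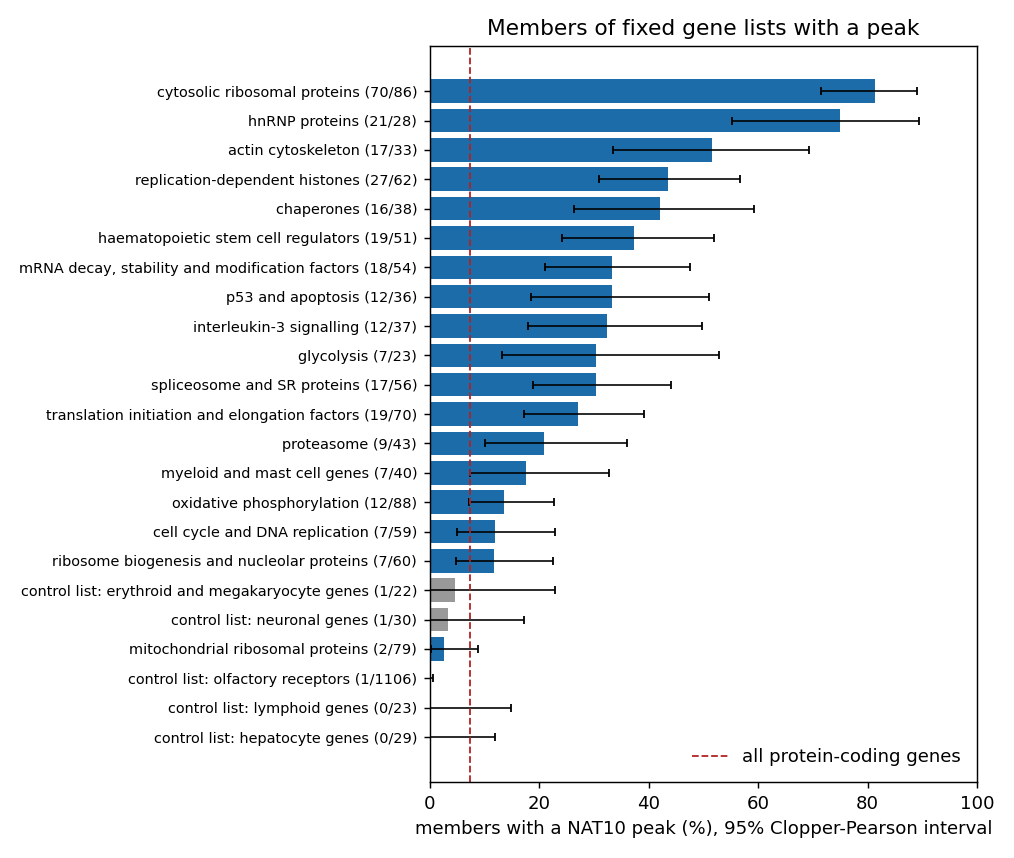
Percent of members with a NAT10 peak (horizontal axis) for the 23 gene lists, with 95% Clopper-Pearson intervals as error bars and members bound over members in brackets; control lists are grey and the dashed line is the share of all protein-coding genes, 7.33%. Cytosolic ribosomal proteins (81.4%) and hnRNP proteins (75%) stand highest.

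Among genes matched to the RefSeq table, RNAs other than nuclear mRNA were rare, apart from mitochondrial transcripts. A further 12 gene identifiers had no match, so their type is unknown. The matched non-coding genes were the lncRNAs Snhg4 with 3 peaks (log2 fold up to 4.96), Tug1 with 2 (up to 4.29) and Kantr with 1 (4.19), and a pseudogene, Rps18-ps6 (4.08). No gene with a peak was of the rRNA, tRNA, snoRNA, snRNA or miRNA type in the RefSeq table, and whether such genes could enter the list is not given in the sources used here. Mitochondrial mRNAs held 61 peaks (1.46%), all on the plus strand, on 6 genes of the respiratory chain: mt-Co1 (16 peaks), mt-Nd5 (15), mt-Nd2 (9), mt-Nd1 (7), mt-Nd4 (7) and mt-Cytb (7). Of the 34 peaks at the p ceiling 19 were mitochondrial. The strongest exon peak per gene had a median log2 fold of 7.81 for these 6 genes, against 4.55 for the 694 nuclear genes with an exon peak. Peaks of those nuclear genes in untranslated regions were left out. The difference of 3.26 had a permutation p of 1e-05, the smallest that 100000 permutations can give. This test treats the 6 genes as independent, though all lie on 1 strand of 1 genome, and it measures no spread between replicates. The mitochondrial genes had 7 to 16 peaks each, more than the median of 2 over all genes. With the median exon peak of each gene the difference was 2.53, at the same smallest permutation p. Folds that fit 1 input read in each library made up 26.2% of mitochondrial peaks and 79.0% of all exon peaks. The folds compared can therefore rest on unlike input counts. Copies of mitochondrial sequence in the nuclear genome can share reads with these genes.

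**Figure D4:**
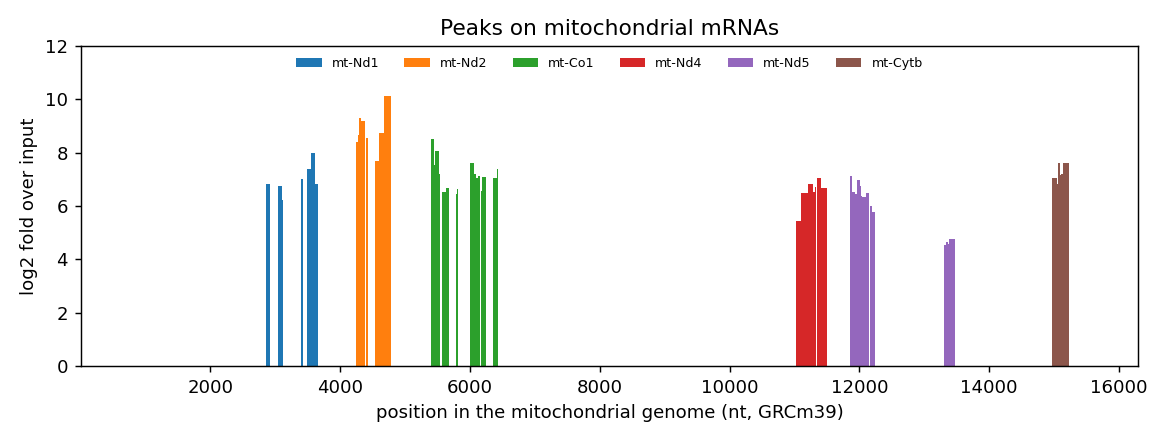
The 61 mitochondrial peaks by position in nt in the mitochondrial genome of GRCm39 (horizontal axis) and log2 fold over input (vertical axis), with 1 bar per peak coloured by gene. The highest bar is mt-Nd2 at 10.12, and no peak lies between mt-Co1 and mt-Nd4.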

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

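No paired analysis was possible because the deposited peak list has no column per library; leaving out a replicate, the agreement of replicates, another normalization or filter, other isoform, centre or strand rules, sequence windows and exonic length matching were not run for the same reason or for want of a genome of the build. The restriction to exonic peaks moved nothing, since the list holds no other class. Merging touching peaks, leaving out mitochondrial peaks, counting bases, matching on gene length, the background of other lists, the demand for 2 regions, and the alternatives for width, mitochondrial genes, list strength, 3' UTR genes and read steps were chosen after seeing the data. Of 155 alternative values for 40 results, 113 kept their direction and side of the threshold or stayed within the interval or 1.5 times the count. The cause was not tested for the changes below.

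The 3' UTR share rose from 57.6% to 59.7% with the stronger peaks, 62.6% with 1 peak per gene and 62.1% of bases, and the exon share was 35.1%, 32.3% and 32.7%. The fold differences between classes, none called, turned or vanished with -log10 p (3' UTR minus exon 0, 3' UTR minus 5' UTR -0.25, exon minus 5' UTR -0.25) and with 1 peak per gene (-0.0083, -0.17 and -0.16). Without mitochondrial peaks 3' UTR minus exon was 0.11 and called.

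Against the other fixed lists, where 18 lists without the controls were tested, 2 had a higher share instead of 14, and 4 had a lower share. The olfactory receptors, the 1 list with a lower share among all 23, were not tested there. There the folds of ribosome biogenesis (0.355), cell cycle (0.362) and oxidative phosphorylation (0.409) turned to below 1 and were called, and those of translation factors (0.853), spliceosome (0.962), glycolysis (0.966), proteasome (0.654) and myeloid genes (0.545) turned and were not; mitochondrial ribosomal proteins, at 0.0741, became called. With the stronger peaks ribosome biogenesis (0.827) and oxidative phosphorylation (0.846) turned, uncalled both times. With 2 or more separate regions per gene the proteasome had no member left (0), the uncalled erythroid list turned to 1.33, and histones (adjusted exact p = 0.232) and mRNA decay factors (0.0649) lost their calls. Matched on gene length, oxidative phosphorylation became called (fold 2.34). With the median instead of the strongest peak per gene, cytosolic ribosomal proteins turned from above to below other bound genes (-0.18, not called). Depth per library is unknown, so peaks under the list's lowest fold and p cannot be weighed.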

Other observations

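All tests in this part were chosen after the results they bear on had been seen. The genes named in the next paragraph were likewise chosen after their values were seen.

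Among genes outside the fixed lists and not named so far, those with 14 or more peaks were taken. Srrm2, a splicing co-activator, had 18 peaks in 11 regions, with a log2 fold of up to 5.84. Ogt, the enzyme that adds O-linked GlcNAc to proteins, had 15 peaks in 10 regions (up to 5.98), the membrane protein gene Serinc3 had 15 in 13 regions (up to 6.63) and the phosphatase gene Ptp4a2 had 15 in 11 regions (up to 5.84). Cd47, the cell-surface signal that holds back phagocytosis, had 14 in 9 regions (up to 6.76), and Slc18a2, the vesicular monoamine transporter, had 14 in 10 regions (up to 6.69). Fnbp1 (up to 5.73) and Rack1, which encodes a scaffold protein of the small ribosomal subunit (up to 5.56), each had 14 in 11 regions. No function common to these genes was tested.

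Gene symbols that share their leading letters were tested as families, 152 with at least 15 genes (Fisher's exact test with adjustment over the families). Of these 6 had a higher share of bound genes than the rest and 3 a lower share. The lower ones were Gm (2 of 1329), Olfr (1 of 1110) and Vmn symbols (0 of 355), which are part of the background of the other families. Besides Rpl, Rps and Eif, the higher ones were Cdk symbols (8 of 26, fold 4.21, adjusted exact p = 0.0078), Ppp symbols, mostly subunits of protein phosphatases (15 of 77, fold 2.67, adjusted p = 0.0078), and Rab symbols, small GTPases of membrane traffic (13 of 69, fold 2.58, adjusted p = 0.0229). No other background was tried for the families, so these calls are not separated from broad expression of their genes.

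The share of bound members differed widely between gene lists. Apart from the control lists, it ran from 81.4% of cytosolic ribosomal proteins to 2.53% of mitochondrial ones. The tables argue against the genomic span of genes, introns included, as the whole cause. Of the 14 lists with a higher share, 13 kept their call against 10000 random lists matched on that span. Length of the mature mRNA, where all listed peaks lie, was not matched and stays open. Transcript abundance stays open and may contribute: lists with a larger share of bound members had a smaller share of peaks whose folds fit 1 input read per library, as described for the fold steps below (Spearman's rho -0.563, permutation p = 0.0203; Pearson's r -0.542, p = 0.0227; 17 lists that share some genes, 1 relation computed). Without the 2 lists farthest from the median, actin cytoskeleton and proteasome, rho was -0.463 (p = 0.0833) and r was -0.492, so the relation rests partly on those. No biological explanation was tested, as the design has no second condition.

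Of 12 mitochondrial mRNAs of the heavy strand 6 had a peak and 6 did not, and those without (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) are all neighbours. No peak lay from position 6440 to 11030, and the next longest stretch between peaks was 1504 nt. The 6 without a peak are also the 6 shortest of the 12, so mRNA length is a candidate explanation for which genes lack a peak. Length was compared per gene only. It does not address where the stretch begins, after the last mt-Co1 peak, and ends, before the first mt-Nd4 peak. Another candidate explanation is a nuclear copy of this part of the mitochondrial genome, whose reads would map to both places and could be dropped. The stretch of 4591 nt would have to be compared with the nuclear genome, which was not used here, so this cannot be told apart from a true lack of binding. No biological explanation was tested.

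The authors' folds fell on steps. If each fold is the mean of the log2 folds of 2 library pairs with 1 input read in each, 4 raised to the fold is a constant times the product of 2 read counts. With a log2 fold of 4.05 set to a product of 90, 82.6% of peaks (3447) gave a whole product within 0.001. Over 1000 random settings the mean share was 0.205% and the highest 33.2%. The 90 was searched for, as the smallest whole number that left most products whole. The random settings were not searched, so the comparison is uneven. For most peaks the folds could rest on a minimal input count of 1 in each library. The steps do not show whether that was an actual read. With a product of 90, the geometric mean of their immunoprecipitate reads would have a median of 14.5, and 68.4% would lie under 20 reads. A multiple of 90 would raise these counts. The share of peaks with a whole product was 85.9% in 3' UTRs, 79.0% in exons, 72.2% in 5' UTRs and 26.2% for mitochondrial peaks. No biological explanation was tested.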
